A study of Mus musculus with 9 samples.

How the data were processed

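Lung RNA of 9 mice in 3 groups of 3 was compared, with saline, LPS with vehicle and LPS with RSBD as the groups. Per the labels' protocols, mRNA was enriched, strand-specific libraries were made, and paired-end reads of 150 bases were sequenced on an Illumina NovaSeq. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1, StringTie 2.2.0 and DESeq2 1.38.3 were used with the mouse genome GRCm38 (mm10), and the notes give no role or order of the tools. The counter and the annotation release are not given in the sources used here. The deposited table of the authors holds estimated counts per gene (expected counts), which are whole numbers in every cell, so no value was rounded here. The deposited TPM values, made by the authors for the same genes, served for alternatives only. Both tables hold 21930 genes, all protein-coding, so other RNA classes were not analysed here. Of these 3511 had no read in any library, and 31 symbols are shared by several identifiers. TPM columns sum to between 795528 and 859032, and 0 of 197370 cells were zero in one table only. TPM per read was off by over 10% of the gene's usual value in 3.02% of values over 10872 genes. Coordinates are those of the deposited table, and 21688 of the 21888 identifiers found in GENCODE M21 have the same coordinates there. Reads of overlapping gene models may be assigned to either.

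Columns were matched to libraries by group and replicate number, those of the LPS plus RSBD group by elimination. A few genes are not reported here. All 9 libraries were kept. No batch is given, and the replicate numbers were not used in the main fit. Total counts per library ranged from 26959662 to 36113905. At this depth the fitted log2 fold changes had a median SE of 0.15, and the common biological coefficient of variation was 0.19.

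Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 15636. Libraries were scaled by TMM and all 9 were fitted in a single quasi-likelihood model with robust estimation and group as the factor. The comparisons were LPS with control, LPS plus RSBD with LPS, and LPS plus RSBD with control, each by the 2-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM were TMM-scaled over tested genes. For genes with 2 or fewer control reads the text gives a ratio with an exact Poisson 95% interval, or a lower bound against a floor of 3 reads (near the 1-sided upper 95% Poisson limit for 0 reads), in place of a fitted fold change. These cover counting error only and take reads as independent. Values of 2 outnumber values of 1 in the count table (2989 against 1349), so reads may not be independent and these limits may be too narrow. Group scores were compared by exact 2-sided permutation, where 3 against 3 cannot go below 0.1.

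A set of 40 gene lists was tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 genes tested, with adjustment over lists within a comparison. The lists are cell types (alveolar type 1 and 2, transitional, club, ciliated, endothelium, fibroblasts, smooth muscle, mesothelium, neutrophils, monocytes, alveolar macrophages, dendritic, T, B, plasma, NK, eosinophils with basophils and mast cells), pathways (cytokines and NF-kB targets, type I interferon, interferon gamma, inflammasome, oxidative stress, T helper regulators, complement, junctions, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, xenobiotic and glucocorticoid response, cell cycle), other tissues (cardiac, skeletal, adipose, thymus, erythroid) and technical signs (immediate early, mitochondrial and clock genes). Camera asks whether a list moves relative to the other genes. It was repeated with the correlation estimated from the data, under which the circadian clock list in LPS plus RSBD against LPS kept its call and no other list did. Fry tests each list on its own by rotation. Counts of members past the threshold are given adjusted over all genes and adjusted over the list alone. A list score is the mean log2 CPM (prior count 2) of members minus its mean over the 9 libraries.

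The groups, main test, lists, alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison, the 6 higher and 6 lower called genes with the largest fold change, non-overlapping groups and a mean of at least 5 CPM, leaving out unnamed models. It adds the 2 members with the smallest p of up to 10 called lists, 13 fixed genes (Tnf, Il1b, Il6, Cxcl1, Ccl2, Nos2, Saa3, Lcn2, S100a8, S100a9, Sftpc, Ager, Scgb1a1) and genes called in opposite directions, of which there were 0. It gave 78 genes. Other genes are named as members of a list, as genes of chromosomes X and Y or as clock and retinoid genes, and were chosen after the data were seen.

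Alternatives were DESeq2 1.42.0, limma-trend on log2 TPM with pseudocounts 1 and 0.1 (genes with a TPM of at least 1, or no filter), RLE scaling, no filter, at least 50 reads in 3 libraries, the 6 compared libraries alone, the replicate number as a block, each library left out in turn, and a fold change of at least 2. A test without the genes of chromosomes X and Y was added after the data were seen. Where comparisons share libraries, 20 simulated sets with unchanged groups, or with an LPS effect alone, give the value expected from sharing. All simulated data draw each gene independently, so their spread may be too narrow. Unchanged groups gave at most 2 calls per comparison, so they give no reference for a measure that rests on called genes. The test was tested on simulated data with 200 planted changes, 50 at each fold, and a list of 25 further genes raised 1.5-fold. At 1.5-, 2-, 3- and 4-fold it recovered 24, 68, 74 and 82% in LPS against control, 26, 74, 80 and 88% in LPS plus RSBD against LPS, and 36, 48, 80 and 94% in LPS plus RSBD against control. Of 142, 151 and 140 calls 11, 10 and 7 were false, that is, of genes in neither planted set. The recoveries cover the 200 genes and not the list.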

Results

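Lung RNA from 9 mice was sequenced in 3 groups of 3, each library being a separate biological replicate per the series' design text. Acute lung injury was induced with lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria that activates innate immune cells, placed in the trachea at 2 mg/kg. Control mice received saline in its place. From the day after LPS, mice were gavaged daily with vehicle or with a decoction of Renshen Baidu Powder (RSBD), a traditional Chinese herbal formula, and lungs were taken on day 5 after LPS. The labels give 5 daily doses, which fit only if the last was given on the day of collection, so the number of doses received is unclear. The labels describe every animal as a male C57BL/6 mouse of 6 to 8 weeks. The design asks which lung transcripts differ after LPS, and whether RSBD moves those transcripts or others. Total counts over protein-coding genes were 28655991, 31003253 and 27789513 in control libraries 1 to 3. They were 26959662, 31227237 and 27746673 in LPS libraries 1 to 3, and 36113905, 30680533 and 27736442 in LPS plus RSBD libraries 1 to 3 (called RSBD 1 to 3 below). The 10 most abundant genes took 6.26% to 8.4% of the counts of a library, and mitochondrial transcripts 2.21% to 3.36%. Levels are in CPM (counts scaled to a library size of 1e+06), given as mean ± SD with n = 3 libraries per group, and fold changes are log2 ± SE from edgeR's quasi-likelihood fit with Benjamini-Hochberg adjusted p over 15636 genes. The median SE of a log2 fold change was 0.15 in each comparison.

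Genes of chromosome Y set the 3 libraries labelled control apart from the other 6, although the labels give every mouse as male. Ddx3y, an RNA helicase gene of chromosome Y (ENSMUSG00000069045, 1260771 to 1286629 on mm10), had 0 reads in all control libraries, 108 ± 12.5 CPM in LPS libraries and 106 ± 4.54 CPM in LPS plus RSBD libraries. Against a floor of 3 reads over the control group, it was at least 3154-fold higher in LPS and at least 3094-fold higher in LPS plus RSBD libraries. Eif2s3y, a translation initiation factor gene (chromosome Y, 1010543 to 1028847), was at least 3442-fold and at least 3093-fold higher, and Uty, a histone demethylase family gene (1096861 to 1245759), at least 812-fold and at least 869-fold higher. Kdm5d, a histone demethylase gene (897788 to 956786), had 2 control reads, and its ratio to control was 2250 in LPS libraries (95% exact Poisson interval 623 to 18600) and 2360 in LPS plus RSBD libraries (652 to 19500). Reads of all genes of chromosome Y numbered 6, 7 and 9 in the control libraries and 7511 to 10918 in the others. Such intervals and floors cover counting error only, with reads taken as independent. Kdm5c and Kdm6a, X-linked genes that escape X inactivation, fell in LPS libraries against control by 0.87 ± 0.11 and 0.75 ± 0.08 (edgeR adjusted p = 0.00289 and 0.00198). Eif2s3x and Ddx3x, also known to escape in the mouse, fell by 0.39 ± 0.08 and 0.51 ± 0.09 (adjusted p = 0.0132 and 0.00834). Every comparison with the control libraries is therefore also a comparison of libraries without and with chromosome Y transcripts, and no library of this set separates the pair of factors.

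**Figure D1:**
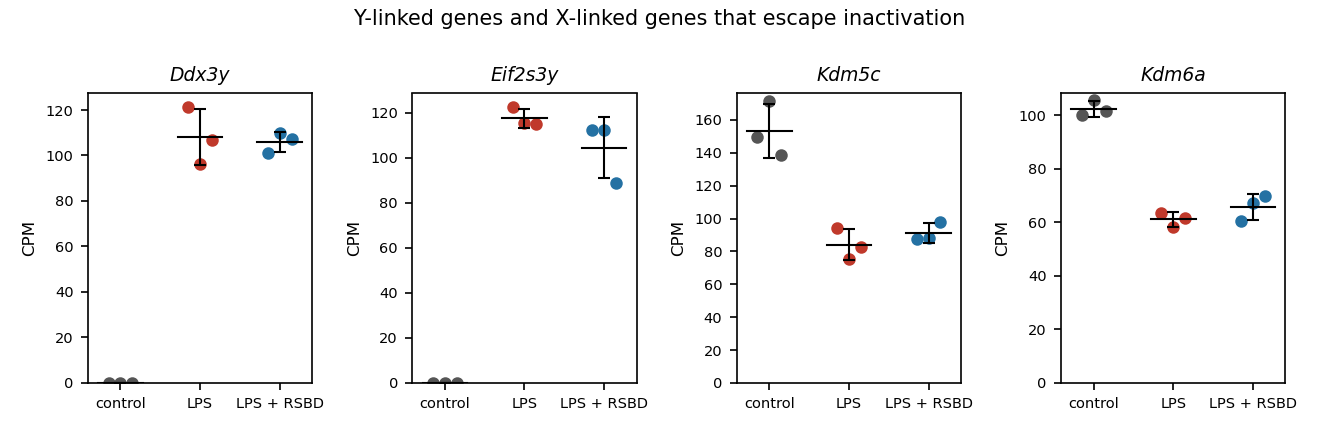
CPM of Ddx3y, Eif2s3y, Kdm5c and Kdm6a in each library by group on linear axes; points are libraries, horizontal lines are means and bars are SD (n = 3). The control libraries sit at 0 CPM for Ddx3y and Eif2s3y, and above all others for Kdm5c and Kdm6a.

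Compared with lungs labelled control, LPS lungs on day 5 held more transcripts of natural killer (NK) cells, dividing cells, macrophages and the joint group of eosinophils, basophils and mast cells, and fewer of the airway epithelium and of immediate early genes, by camera at its preset correlation. None of these list calls was kept with an estimated correlation (adjusted p from 0.113 to 0.69). Ncr1, an activating receptor of NK cells (chromosome 7, 4337724 to 4345164), rose from 1.53 ± 0.517 to 6.22 ± 2.06 CPM, a log2 fold change of 2.02 ± 0.32 (edgeR adjusted p = 0.00553). Bpifb1, a secreted protein of airway epithelium (ENSMUSG00000027485, chromosome 2, 154190818 to 154220369), fell from 41.3 ± 27.02 to 4.59 ± 0.778 CPM, a change of -3.17 ± 0.47 (adjusted p = 0.00557). Egr1, an immediate early transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), fell from 69.3 ± 22.1 to 12.95 ± 3.496 CPM, a change of -2.42 ± 0.27 (adjusted p = 0.00282). Over all genes, 1374 were higher and 1349 lower, 2723 in total, of which 335 and 262 differed by at least 2-fold. Genes on chromosomes X and Y made up 72 and 4 of the calls, and 2647 lay elsewhere. The groups did not overlap for 38% of the genes, where chance gives 10%. The count of calls moved by more than 1.5 times when a library was left out, to 892 without control 2, 999 without control 3, 786 without LPS 2 and 1631 without LPS 3. Limma on log2(TPM + 1) split its 2049 calls into 711 higher and 1338 lower.

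Beside the genes of chromosome Y, the largest increases among named genes with a mean of at least 5 CPM in the higher group and no overlap between groups were those of Ngp, a granule protein of immature neutrophils (chromosome 9, 110419747 to 110423012), and Ifitm6, an interferon-induced transmembrane protein gene (chromosome 7, 141015699 to 141017924). Ngp measured 51.9 ± 50.5 CPM in control and 523 ± 272 CPM in LPS libraries (3.33 ± 0.87, adjusted p = 0.034), and Ifitm6 30.4 ± 15.6 and 231 ± 114 CPM (2.93 ± 0.70, adjusted p = 0.0258). The largest decrease was that of Cyp26b1, an enzyme that breaks down retinoic acid (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908). It measured 1254 ± 869 CPM in control and 40.5 ± 41.7 CPM in LPS libraries (-4.95 ± 0.88, adjusted p = 0.0094). Bpifa1 and Reg3g, secreted defence proteins of the airway, fell by 4.17 ± 0.90 and 4.05 ± 0.61 (adjusted p = 0.0178 and 0.00576). Gp2, a receptor for bacteria on M cells, fell by 4.005 ± 0.78, Fgg, the fibrinogen gamma chain, by 3.57 ± 0.53, and A2ml1, a protease inhibitor, by 3.52 ± 0.75 (adjusted p = 0.0129, 0.00557 and 0.0168). Calls were lost for Ngp without control 1 or 2, any LPS library or RSBD 2 or 3, and for Ifitm6 without any control library, LPS 1, LPS 2 or RSBD 2, and for both with no filter on low counts (highest adjusted p = 0.0924 and 0.0767). Those of Bpifa1 and A2ml1 were lost without control 3 or any LPS library (highest adjusted p = 0.0919 and 0.0894), and that of Gp2 without LPS 3 (0.0653).

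Of the 19 genes of the NK cell and cytotoxic list, 11 rose, 0 fell and 8 did not pass (14 higher adjusted over the list alone). Its median log2 change was 1.06 (camera adjusted p = 2.81e-08, and adjusted p = 0.377 with an estimated correlation). Gzmb, the cytotoxic granule protease granzyme B, rose from 2.46 ± 0.376 to 10.01 ± 1.896 CPM (2.02 ± 0.33, adjusted p = 0.00666), and Klrb1c, the NK1.1 receptor, by 1.69. In the eosinophil, basophil and mast cell list, 6 of 14 genes rose (8 adjusted over the list alone; median 1.04, camera adjusted p = 2.79e-05, adjusted p = 0.113 with an estimated correlation). They were the basophil protease Mcpt8, the basophil receptor Cd200r3, the eotaxin receptor Ccr3, the mast cell protease Cpa3, Siglecf, which alveolar macrophages also carry, and Ms4a2, the beta chain of the IgE receptor. Ms4a2 had 2 control reads and a ratio to control of 48.6 (95% exact Poisson interval 13.1 to 407). Of 27 cell cycle genes 13 rose (19 adjusted over the list alone; median 0.99, camera adjusted p = 1.33e-07, adjusted p = 0.666 with an estimated correlation). Ccnb1, the mitotic cyclin B1, rose from 2.08 ± 0.736 to 6.76 ± 1.41 CPM (1.70 ± 0.37, adjusted p = 0.0152), and Mcm5, a DNA replication helicase subunit, by 0.95 ± 0.23 (adjusted p = 0.0225; lost without any control library or LPS 2, highest 0.0677).

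Alveolar macrophage genes rose in 8 of 22 cases (11 adjusted over the list alone; median 0.60, camera adjusted p = 1.59e-05, adjusted p = 0.535 with an estimated correlation). Abcg1, a cholesterol exporter, rose from 75.5 ± 3.76 to 126 ± 3.93 CPM (0.73 ± 0.09, adjusted p = 0.00282), Ear2, an eosinophil-associated ribonuclease, by 1.51 ± 0.25 (adjusted p = 0.00753), and Siglecf by 1.11 ± 0.20 (adjusted p = 0.00906). Of 25 monocyte and recruited macrophage genes 9 rose (10 adjusted over the list alone; median 0.49, camera adjusted p = 9.88e-05, adjusted p = 0.535 with an estimated correlation), among them the chemokine receptor Ccr2 by 1.36 and the macrophage elastase Mmp12 by 2.23. The neutrophil list was higher by a median of 1.09 (camera adjusted p = 0.00137, adjusted p = 0.704 with an estimated correlation), with Ngp and Camp, the cathelicidin gene, called of 22 and 0 adjusted over the list alone. That list's call was lost without LPS 1 (adjusted p = 0.0675). Its score per library was -0.171, -1.15 and 0.603 in control and 1.84, 1.46 and 0.232 in LPS libraries, so the groups overlapped. T cell genes were higher by a median of 0.40, with 2 of 19 called (1 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.704 with an estimated correlation). Erythroid genes were higher by a median of 1.74, with 2 of 13 called (3 adjusted over the list alone; camera adjusted p = 8.81e-05, adjusted p = 0.535 with an estimated correlation). Erythroid scores were -1.63 and -1.87 in control 1 and control 2, against 0.127 in control 3 and 0.348 or more in all other libraries.

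**Figure D2:**
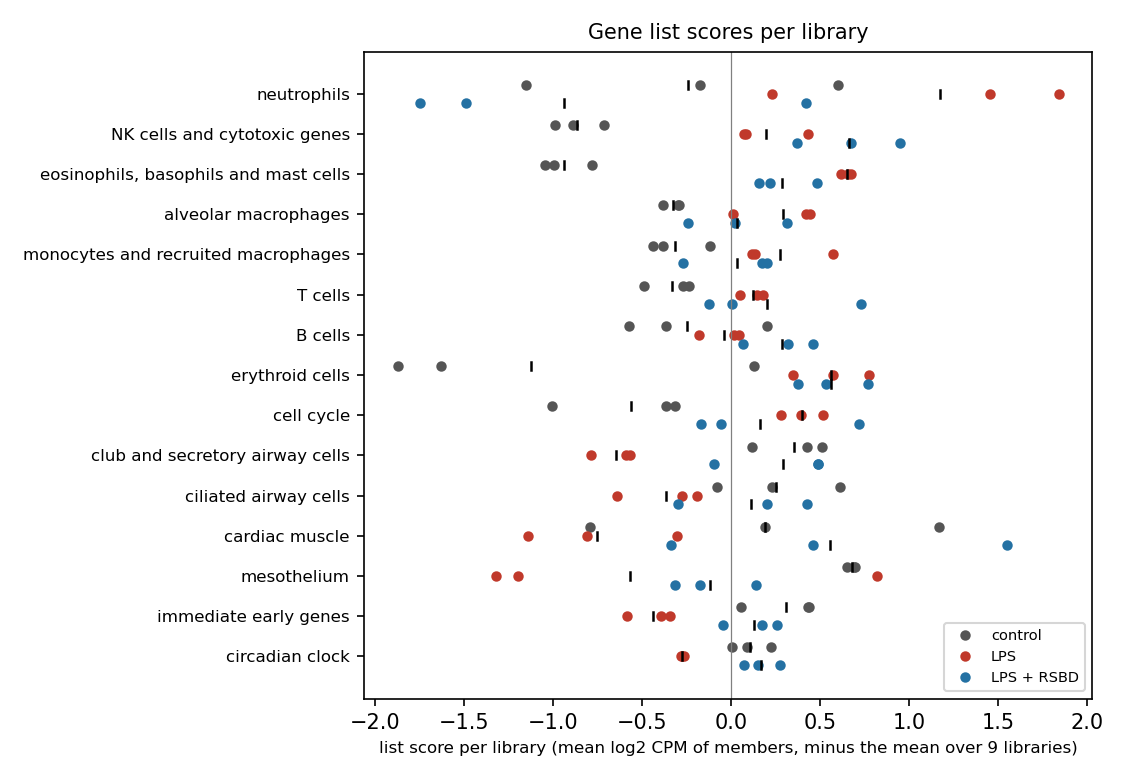
Score of 15 gene lists in each library (horizontal axis, mean log2 CPM of the members minus the mean over the 9 libraries); points are libraries coloured by group and black ticks are group means. The NK list scores run from -0.987 to -0.715 in control libraries and from 0.076 to 0.951 in the others, while the neutrophil scores of the 3 groups overlap.

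Interferon gamma and MHC class II genes rose in 7 of 25 cases (8 adjusted over the list alone; median 0.72, camera adjusted p = 3.58e-05, adjusted p = 0.69 with an estimated correlation). H2-DMa, which loads peptides on MHC class II, rose by 0.98 ± 0.18 (adjusted p = 0.0094). H2-Aa, an MHC class II chain, rose by 1.01 ± 0.25 (adjusted p = 0.0296; lost without any control library, LPS 2 or LPS 3, highest 0.0957). Inflammasome genes rose in 6 of 15 cases (12 adjusted over the list alone; median 0.62, camera adjusted p = 3.44e-05, adjusted p = 0.535 with an estimated correlation), with the cytokine Il18 rising from 5.99 ± 1.06 to 12.8 ± 0.46 CPM (1.09 ± 0.19, adjusted p = 0.00807) and the adaptor Pycard by 0.74 ± 0.15 (adjusted p = 0.0137; lost without control 2 or LPS 2, highest 0.0602). In the type I interferon list 3 of 28 rose and 0 adjusted over the list alone (median 0.59, camera adjusted p = 0.000116, adjusted p = 0.704 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 9 of 29 cases (10 adjusted over the list alone; median 0.30, camera adjusted p = 3.38e-05) and mitochondrially encoded transcripts in 5 of 13 (12 adjusted over the list alone; median 0.49, camera adjusted p = 6.19e-05). Both had an adjusted p = 0.69 with an estimated correlation. Uqcrfs1, a subunit of respiratory complex III, rose by 0.46 ± 0.09 (adjusted p = 0.00958) and Cox5b, of cytochrome c oxidase, by 0.52 ± 0.11 (adjusted p = 0.0165; lost without control 2, control 3 or LPS 2, highest 0.0655).

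Airway epithelial genes were lower in LPS lungs. Of 22 club and secretory cell genes 10 fell (10 adjusted over the list alone; median -0.47, camera adjusted p = 1.3e-05, adjusted p = 0.535 with an estimated correlation), including Muc5b, the main gel-forming mucin of mouse airways, by 2.41. Of 22 ciliated cell genes 8 fell (13 adjusted over the list alone; median -0.77, camera adjusted p = 1.28e-05, adjusted p = 0.69 with an estimated correlation). Among these were the ciliary dynein heavy chains Dnah9, from 71.8 ± 19.9 to 38.4 ± 1.57 CPM (-0.90 ± 0.22, adjusted p = 0.0267), and Dnah11 (-0.82 ± 0.21, adjusted p = 0.0283). Both of these calls were lost without control 2, control 3, LPS 2 or LPS 3, and Dnah9 also without LPS 1 (highest 0.086 and 0.094). Alveolar type 2 cell genes fell in 4 of 22 cases (4 adjusted over the list alone; median -0.28, camera adjusted p = 0.00616, adjusted p = 0.711 with an estimated correlation; list call lost without control 2 or LPS 1, highest 0.0761), namely Il33, Chia1, Sftpd and Slc26a9. The surfactant gene Sftpc measured 8304 ± 1062 and 9152 ± 2395 CPM and was not called (adjusted p = 0.673). Among genes of other tissues, cardiac muscle and adipose lists were lower in the same libraries, the erythroid list was higher as given above, and skeletal muscle and thymus were not called (medians 0.21 and 0.48). The cardiac muscle list, whose cells also sheath pulmonary veins in the mouse, had a median of -0.98 with Ttn the member called of 18 and 0 adjusted over the list alone (camera adjusted p = 0.00864, adjusted p = 0.728 with an estimated correlation; lost without control 3 or LPS 1, highest 0.15). Adipose genes fell in 3 of 12 cases (4 adjusted over the list alone; median -0.65, camera adjusted p = 0.0344, adjusted p = 0.69 with an estimated correlation; lost without control 3 or LPS 1, highest 0.0781). Of 12 mesothelial genes Msln fell and 0 passed adjusted over the list alone (median -0.31, camera adjusted p = 0.0228, adjusted p = 0.69 with an estimated correlation; lost without LPS 2 or LPS 3, highest 0.0886). The mesothelial score of LPS 1, 0.82, lay above the control scores of 0.653 to 0.698, while LPS 2 and LPS 3 were at -1.321 and -1.194.

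Immediate early genes fell in 8 of 23 cases (1 higher and 10 lower adjusted over the list alone; median -0.42, camera adjusted p = 1.59e-05, adjusted p = 0.377 with an estimated correlation). They included Fos, from 46.8 ± 14.7 to 22.7 ± 4.58 CPM, and the heat shock gene Hspa1b, from 17.5 ± 6.52 to 3.23 ± 0.73 CPM (-2.44 ± 0.32, adjusted p = 0.00326). Circadian clock genes fell in 9 of 18 cases (10 adjusted over the list alone; median -0.39, camera adjusted p = 0.000527, adjusted p = 0.269 with an estimated correlation), among them Per2 by 1.22 and Hlf by 0.71. Cholesterol and fatty acid synthesis genes fell in 7 of 23 cases (10 adjusted over the list alone; median -0.37, camera adjusted p = 4.65e-05, adjusted p = 0.69 with an estimated correlation). Unfolded protein response genes fell in 4 of 20 cases (8 adjusted over the list alone; median -0.30, camera adjusted p = 0.0021, adjusted p = 0.69 with an estimated correlation; list call lost without LPS 1, 0.0652).

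Classical inflammatory cytokine genes did not move one way on day 5. Of 31 cytokines and NF-kB targets Nos2, the inducible nitric oxide synthase, rose from 3.74 ± 1.57 to 10.5 ± 3.69 CPM (1.498 ± 0.39, adjusted p = 0.0299), and Il1rn and Tlr2 also rose. Il6 and Cd14 fell, Il6 from 2.27 ± 1.53 to 0.654 ± 0.12 CPM (-1.79 ± 0.55, adjusted p = 0.0477). The list as a whole was not called (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.633). Nos2 lost its call without control 1, control 2, LPS 1 or LPS 2 (highest 0.106) and Il6 whichever library but control 1 was left out (highest 0.187). Lcn2, an iron-sequestering acute phase protein, measured 306.5 ± 82.0 and 549 ± 137 CPM (0.84 ± 0.26, adjusted p = 0.056, and called without RSBD 2, 0.0371, with 0.00493 to 0.172 over all alternatives). The log2 fold changes of the neutrophil alarmins S100a8 and S100a9 were 1.85 and 1.84 (adjusted p = 0.137 and 0.128). Il1b, Tnf, Ccl2, Cxcl1 and Saa3 differed by 0.25, 0.43, -0.25, -1.01 and 0.75 (adjusted p from 0.322 to 0.85). Ager, of alveolar type 1 cells, and Scgb1a1, of club cells, differed by 0.10 and -0.41 (adjusted p = 0.636 and 0.186).

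The remaining lists were not called in LPS against control lungs, with camera adjusted p from 0.155 to 0.998. Calls among their members went both ways for alveolar type 1 cells (2 higher and 3 lower of 19), transitional epithelium (1 and 3 of 20), dendritic cells (4 and 2 of 21), endothelium (4 and 1 of 25), fibroblasts (2 and 1 of 29), junctions (3 and 2 of 21), Nrf2 targets (3 and 4 of 27), glucocorticoid response (2 and 2 of 19) and complement (1 and 1 of 26). Krt8, Sfn and Hbegf of the transitional list fell and Lgals3 rose. The test pointed up against a negative median for cytokines and down against a positive median for T helper regulators, and the mean of the fibroblast list was below 0 with its median above. B cells and thymus had 1 higher of 17 and 1 higher of 7, T helper regulators 1 lower of 16, xenobiotic response 4 lower of 19, and plasma cells, smooth muscle and skeletal muscle 0 of 9, 16 and 8. In all, 23 of 40 lists were called, 13 higher and 10 lower. With an estimated correlation 0 remained past the threshold, and fry called 6 (NK, immediate early, club, alveolar macrophage, clock, and the eosinophil, basophil and mast cell list).

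RSBD lungs held less neutrophil transcript and more airway secretory, immediate early and clock transcript than LPS lungs as lists, while 0 genes passed alone by edgeR. Of these 4 lists the clock kept its call with an estimated correlation (adjusted p = 0.0179) and neutrophils, club cells and immediate early genes did not (adjusted p = 0.342, 0.209 and 0.083 with an estimated correlation), and the neutrophil scores of the groups overlapped. The clock and immediate early lists had been set beforehand as technical signs. Camp, the cathelicidin gene of neutrophil granules (chromosome 9, 109847379 to 109849617), measured 72.0 ± 30.6 CPM in LPS and 4.45 ± 3.05 CPM in LPS plus RSBD libraries, with 10.3 ± 9.98 CPM in control (log2 fold change RSBD over LPS -4.04 ± 0.81, adjusted p = 0.331). Egr1 measured 12.95 ± 3.496 and 63.5 ± 11.5 CPM (2.29 ± 0.27, adjusted p = 0.205, the smallest of all genes). Bpifb1 measured 4.59 ± 0.778 and 33.2 ± 4.53 CPM (2.85 ± 0.46, adjusted p = 0.284). At an unadjusted p under 0.05 there were 1473 genes where chance gives 782, and the groups did not overlap for 12.6% of genes where chance gives 10%. DESeq2 called 154 genes, 92 higher and 62 lower, with Egr1 and Fos at its smallest adjusted p (9.18e-16 and 6.77e-07, against 0.205 and 0.284 by edgeR). Limma on log2(TPM + 1) called 1 gene, Egr1 (adjusted p = 0.0321). A fit of the 6 libraries alone called 1, Bpifb1 (0.00261). Leaving out a control library, which enters neither group here, gave 4 calls without control 1 (Gp2, Fos, Muc5b and Bpifb1) and 2 without control 2 (Egr1 and Per3), named here after their values were seen. Over all alternatives the adjusted p ranged from 9.18e-16 to 0.483 for Egr1, from 6.77e-07 to 0.584 for Fos and from 3.76e-05 to 0.795 for Bpifb1. In simulated data with many planted changes edgeR recovered 74% of genes changed 2-fold in this comparison, with 151 calls. The Benjamini-Hochberg cutoff on the unadjusted p is looser with 151 calls than with 0. The 74% is therefore not the recovery behind the 0 calls here, and changes of 2-fold or more may have been missed. Egr1, Bpifb1 and Camp differed by more than 2-fold and did not pass.

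Neutrophil genes were lower by a median of 1.72 log2 units (log2 fold change -1.72; 22 genes, camera adjusted p = 4e-19, adjusted p = 0.342 with an estimated correlation), with Ngp and Camp lower adjusted over the list alone. Ngp measured 523 ± 272 and 31.3 ± 24.3 CPM (-4.07 ± 0.91, adjusted p = 0.348), and the changes of S100a8 and S100a9 were -2 and -1.82 (adjusted p = 0.5 and 0.518). Neutrophil scores were 1.84, 1.46 and 0.232 in LPS and -1.75, -1.49 and 0.422 in LPS plus RSBD libraries, so RSBD 3 lay above LPS 3. The difference of the means, -2.11, had an exact 2-sided permutation p = 0.2. Alveolar macrophage genes had a median of -0.22 (camera adjusted p = 0.000951, adjusted p = 0.511 with an estimated correlation; call lost without LPS 3, 0.0836). Abcg1 measured 99.2 ± 11.1 CPM with RSBD (-0.34 ± 0.09, adjusted p = 0.382), and Bhlhe41, a transcription factor of that list also counted among clock genes, differed the other way by 0.66. Monocyte genes had a median of -0.23 (camera adjusted p = 0.00227, adjusted p = 0.551 with an estimated correlation; lost without LPS 2 or RSBD 1, highest 0.171). Inflammasome genes had -0.23 (0.00129, adjusted p = 0.551 with an estimated correlation; lost without LPS 1 or RSBD 1, highest 0.154). The median of the eosinophil, basophil and mast cell list was -0.29 (0.0223, adjusted p = 0.342 with an estimated correlation; lost without LPS 1, LPS 3, RSBD 2 or RSBD 3, highest 0.189).

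**Figure D3:**
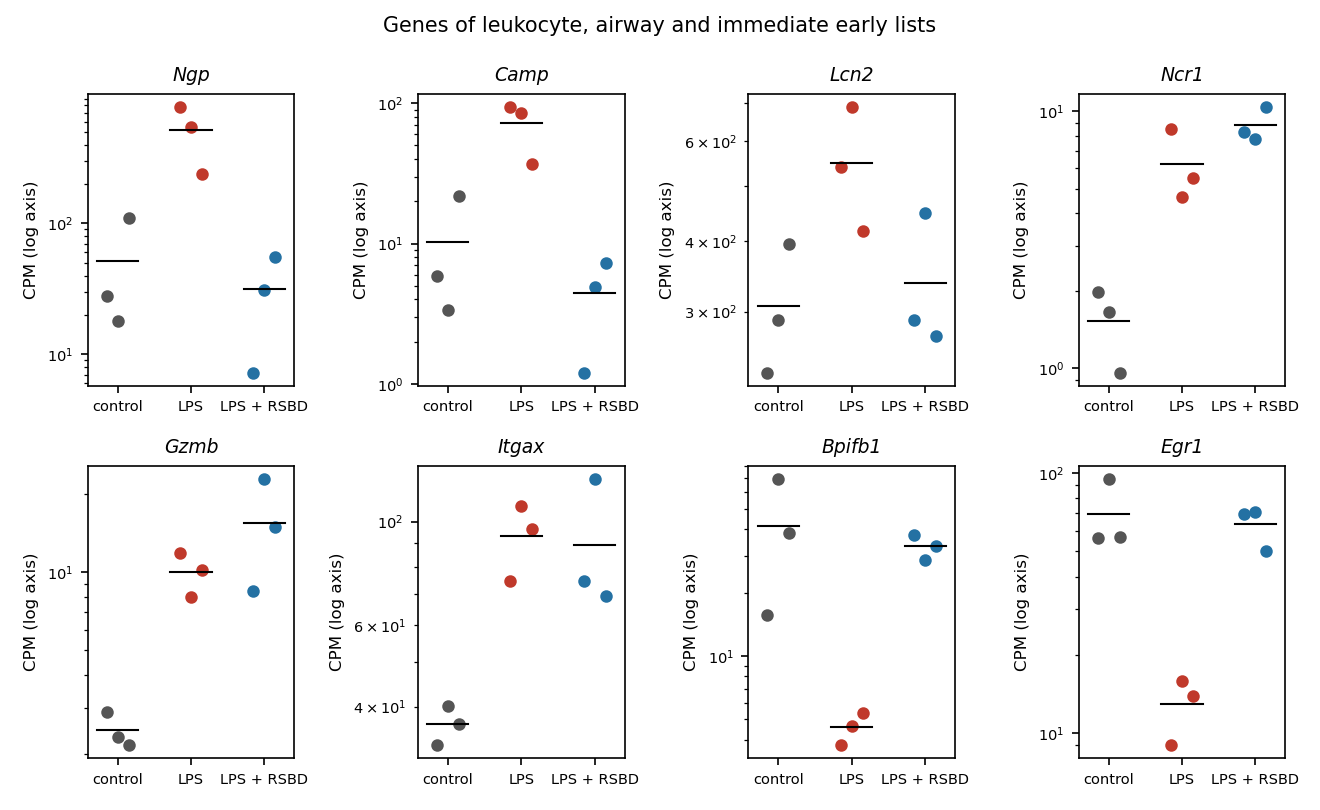
CPM on log axes of 8 genes in each library by group; points are libraries and lines are group means (n = 3). Camp averages 72.0 CPM in LPS and 4.45 CPM in LPS plus RSBD libraries, Ncr1 lies lowest in control, and Bpifb1 and Egr1 lie lowest in LPS libraries.

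NK, B and plasma cell lists were higher in RSBD than in LPS lungs, while the T cell list (median 0.17, camera adjusted p = 0.477) and the thymus and lymphoid progenitor list (0.04, 0.991) were not called. NK cell genes had a median of 0.46 (19 genes, camera adjusted p = 9.36e-06, adjusted p = 0.506 with an estimated correlation), with Gzma, granzyme A, at 20.1 ± 3.04 and 32.9 ± 11.4 CPM (0.71 ± 0.28, adjusted p = 0.487) and the Ly49 family receptor gene Klra4 at 0.89 ± 0.40. B cell genes had 0.38 (17 genes, 0.00013, adjusted p = 0.596 with an estimated correlation) with Blnk, a B cell receptor adaptor, at 0.55 and Pou2af1, a B cell coactivator, at 0.44. Plasma cell genes had 0.40 (9 genes, 0.00129, adjusted p = 0.551 with an estimated correlation; lost without LPS 1 or RSBD 2, highest 0.244), with the transcription factors Irf4 and Prdm1 at 0.51 and 0.39. None of these members passed alone or adjusted over the list alone. NK scores overlapped, with RSBD 1 (0.372) below LPS 1 (0.434). Plasma cell scores did too, with LPS 3 (0.259) above RSBD 1 (0.063) and RSBD 3 (0.044), while B cell scores did not.

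Airway lists were higher in RSBD than in LPS lungs by camera at its preset correlation. Ciliated scores overlapped, with RSBD 2 (-0.296) below LPS 2 (-0.273) and LPS 3 (-0.188), while club and secretory scores did not. The club and secretory list had a median of 0.31 and 9 members higher adjusted over the list alone (22 genes, camera adjusted p = 7.83e-15, adjusted p = 0.209 with an estimated correlation). Muc5b measured 97.3 ± 45.7 CPM in control, 18.3 ± 5.96 in LPS and 108 ± 23.2 in LPS plus RSBD libraries (2.56 ± 0.40, adjusted p = 0.284). The ciliated list had a median of 0.47 with 0 members adjusted over the list alone (22 genes, camera adjusted p = 9.22e-11, adjusted p = 0.511 with an estimated correlation). Its dynein genes Dnah5 and Dnah9 differed by 0.93 ± 0.26 and 0.71 ± 0.22 (adjusted p = 0.393 and 0.408). Cardiac muscle genes moved the same way as the airway lists between these groups. They were higher by a median of 1.48 with Ttn adjusted over the list alone (18 genes, camera adjusted p = 7.08e-11, adjusted p = 0.511 with an estimated correlation), and Myh6, the atrial myosin heavy chain, measured 20.1 ± 6.10 and 119.5 ± 90.6 CPM (2.57 ± 0.78, adjusted p = 0.408). Adipose genes had a median of 0.72 with Cfd and Plin4 adjusted over the list alone (0.00147, adjusted p = 0.511 with an estimated correlation), and smooth muscle genes 0.26 (0.0121, adjusted p = 0.699 with an estimated correlation; lost without LPS 1, RSBD 1 or RSBD 2, highest 0.454). Cardiac scores per library were -1.14, -0.301 and -0.809 in LPS and 1.55, 0.459 and -0.335 in LPS plus RSBD libraries. RSBD 3, with the lowest cardiac score of its group, had the highest ciliated score there (0.425). The cardiac and ciliated orders thus differed in that group of 3 libraries. In control libraries 1 to 3 both lists rose in step (cardiac -0.793, 0.194 and 1.169, ciliated -0.076, 0.233 and 0.61). LPS 1 was lowest of its group in both (-1.14 and -0.639), while LPS 2 and LPS 3 differed in order. Whether the lists share a cause was not tested.

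Immediate early genes had a median of 0.36 and 8 members higher adjusted over the list alone (23 genes, camera adjusted p = 4.52e-14, fry adjusted p = 0.0468, adjusted p = 0.083 with an estimated correlation). Fos measured 22.7 ± 4.58 and 61.9 ± 7.91 CPM (1.45 ± 0.22, adjusted p = 0.284). The circadian clock list was the list that also passed with an estimated correlation (18 genes, median 0.59, camera adjusted p = 3.42e-12, fry adjusted p = 0.0113, adjusted p = 0.0179 with an estimated correlation), with 10 members higher and 1 lower adjusted over the list alone. Hlf and Tef, clock output transcription factors, measured 15.5 ± 2.16 and 35.6 ± 4.14 CPM (1.205 ± 0.19) and 206.5 ± 6.49 and 378 ± 46.6 CPM (0.87 ± 0.14), both with adjusted p = 0.284. The member on the lower side was Arntl (Bmal1), a core activator of the clock, at -1.03 ± 0.22 (adjusted p = 0.331), while its target Dbp stood at 1.79 ± 0.38 (adjusted p = 0.337).

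**Figure D4:**
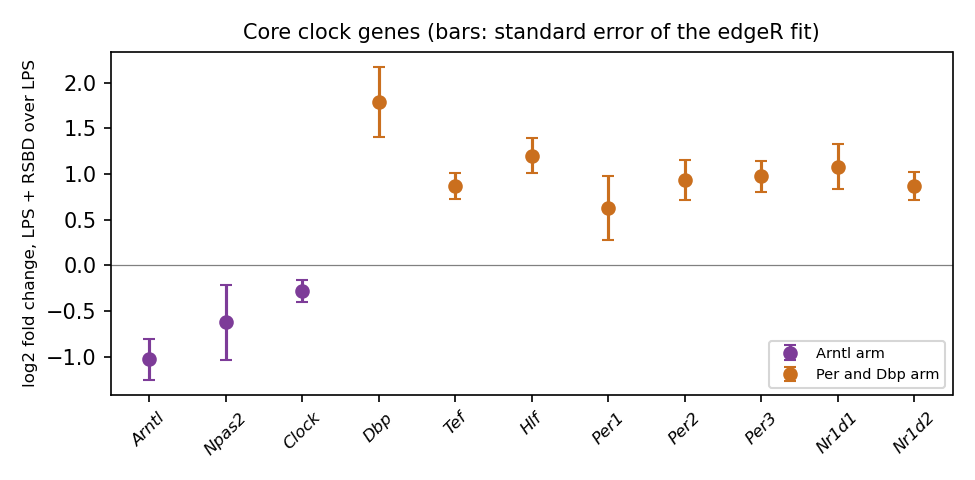
Log2 fold change of 11 clock genes, LPS plus RSBD over LPS (vertical axis), with bars of 1 SE of the edgeR fit. Arntl, Npas2 and Clock lie below 0 (-1.03, -0.62 and -0.28) and the Per, Nr1d, Dbp, Tef and Hlf genes above it, 0.63 to 1.79.

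Further lists called in RSBD against LPS lungs were oxidative phosphorylation (median -0.16, camera adjusted p = 0.00129, adjusted p = 0.699 with an estimated correlation; lost without LPS 2 or LPS 3, highest 0.142) and cholesterol synthesis (0.23, 0.00131, adjusted p = 0.699 with an estimated correlation; lost without LPS 1 or RSBD 1, highest 0.245). Xenobiotic response genes had 0.22 with 2 higher adjusted over the list alone (0.00452, adjusted p = 0.511 with an estimated correlation; lost without RSBD 1 or RSBD 3, highest 0.0715), and cell cycle genes -0.14 (0.0151, adjusted p = 0.813 with an estimated correlation; lost without LPS 1, LPS 3, RSBD 1 or RSBD 3, highest 0.582). In all 19 lists were called, 12 higher and 7 lower, with 1 past the threshold with an estimated correlation and 2 by fry. The other 21 lists had camera adjusted p from 0.0614 (transitional epithelium) to 0.991 (thymus), with mitochondrial, interferon gamma, type I interferon, T cell, erythroid and mesothelial lists among them. The test pointed against the median for cytokines, glucocorticoid response, complement, fibroblasts and thymus, and the mean against the median for the mesothelium. The fixed genes not yet named differed by -0.66 (Nos2), -0.71 (Lcn2), 0.64 (Il1b), -0.52 (Tnf), -0.21 (Il6), 0.79 (Cxcl1), 0.17 (Ccl2), -0.09 (Saa3), -0.03 (Sftpc), -0.04 (Ager) and 0.19 (Scgb1a1), with adjusted p from 0.473 to 0.981.

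Genes called in opposite directions after LPS and after RSBD numbered 0 in the main edgeR fit, which follows from its 0 calls in RSBD against LPS (1473 genes at an unadjusted p under 0.05). Other edgeR fits gave 4 without control 1, 2 without control 2 and 1 with the 6 libraries alone, and DESeq2 gave 129. Of the 2723 genes called after LPS, 2416 (88.7%) had an RSBD fold change pointing back toward control, 1203 of 1374 of those higher and 1213 of 1349 of those lower. Because the LPS libraries enter both differences, simulated data with an LPS effect and no RSBD effect gave 64.5% (63.5 to 65.5 in 20 simulations). These simulations call 3240 genes after LPS (3150 to 3350) against the 2723 observed, so their LPS effect is larger than that of the data, and their values are no exact reference. They also draw each gene independently, whereas genes of a list are correlated in the data. Their ranges may therefore be too narrow. The RSBD change was a median share of -0.32 of the LPS change, where -1 is full return to control. The same simulations gave -0.0908 (-0.0971 to -0.0863) and unchanged groups -0.275 (-0.666 to 0.155). The last range holds -0.32, but it rests on the 0 to 2 genes called per simulated set. It is therefore no reference for a median over 2723 genes. Measured against an LPS library that took no part in choosing the genes, the share was 0.0178 for LPS 1, -0.336 for LPS 2 and -0.143 for LPS 3, so its sign and size depended on the library held out. Across genes, which are not independent replicates, the fold changes of the pair of comparisons correlated at -0.595. Simulations gave -0.496 for unchanged groups (-0.529 to -0.421) and -0.234 for an LPS effect alone (-0.288 to -0.197). The covariance was -0.180, against -0.0546 and -0.0583. Part of this may come from the shared LPS libraries, which cannot be split into groups of 2.

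RSBD lungs compared with lungs labelled control again held more NK cell transcripts and less of the retinoid genes Cyp26b1 and Lrat. The NK list was called by camera at its preset correlation and had an adjusted p = 0.0981 with an estimated correlation, while Gzmb, Ncr1, Klra8, Cyp26b1 and Lrat were called as single genes. Gzmb rose from 2.46 ± 0.376 to 15.4 ± 7.17 CPM (2.64 ± 0.34, edgeR adjusted p = 0.00899), Ncr1 to 8.83 ± 1.39 CPM (2.52 ± 0.32, adjusted p = 0.00899), and Klra8, an activating NK receptor, from 0.763 ± 0.357 to 5.26 ± 2.37 CPM (2.77 ± 0.46, adjusted p = 0.0162). Cyp26b1 fell to 35.7 ± 17.1 CPM (-5.14 ± 0.88, adjusted p = 0.0222) and Lrat, which esterifies retinol, from 261 ± 84.4 to 45.2 ± 7.79 CPM (-2.53 ± 0.32, adjusted p = 0.0105). Entpd8, an ectonucleotidase, fell by 2.55 ± 0.49, Tnfsf9, the 4-1BB ligand, by 2.13 ± 0.28, Hspa1b by 2.08 ± 0.32 and Fosb, an immediate early gene, by 1.99 ± 0.40 (adjusted p = 0.0261, 0.00945, 0.0136 and 0.0338). In total 296 genes were higher and 282 lower, 578 together, of which 19 lay on chromosome X, 4 on Y and 555 elsewhere, and the differences in chromosome Y transcripts apply here too. The groups did not overlap for 30.4% of the genes, where chance gives 10%. Leaving out a library gave 240 calls without control 1, 94 without control 2, 118 without control 3, 961 without LPS 1, 342 without LPS 2, 311 without RSBD 1 and 97 without RSBD 2. DESeq2 called 1702 genes, and limma on log2(TPM + 1) split 308 into 96 higher and 212 lower. Calls were lost for Klra8 without control 2 or 3, for Cyp26b1 without any control or RSBD library, for Entpd8 without any control library or RSBD 1 or 2, for Lrat without RSBD 2, for Hspa1b without control 2 or RSBD 2 and for Fosb without control 2, control 3, LPS 3 or any RSBD library (highest 0.054, 0.13, 0.0895, 0.0634, 0.0555 and 0.0882).

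Of 19 NK cell genes 13 rose in RSBD lungs against control (15 adjusted over the list alone; median 1.5, camera adjusted p = 2.67e-24, fry adjusted p = 0.00635, adjusted p = 0.0981 with an estimated correlation). In the eosinophil, basophil and mast cell list Ms4a2 and Ccr3 rose of 14 (6 adjusted over the list alone; median 0.73, camera adjusted p = 0.000204, fry adjusted p = 0.00153, adjusted p = 0.0981 with an estimated correlation). Ms4a2 had a ratio to control of 77.3 (95% exact Poisson interval 21.1 to 644), and Ccr3 measured 0.24 ± 0.236 and 3.71 ± 1.09 CPM (3.89 ± 0.74, adjusted p = 0.0262). Interferon gamma and MHC class II genes had 2 of 25 higher, H2-DMa (1.02) and the MHC class II transactivator Ciita (0.87), and 10 adjusted over the list alone (median 0.79, camera adjusted p = 2e-07). Type I interferon genes had 2 of 28, Ifi27l2a (1.58) and Dhx58 (1.06), and 9 adjusted over the list alone (0.81, 2.94e-08). The cell cycle list had Mcm5 higher of 27, and 17 higher and 1 lower adjusted over the list alone (0.84, 6.98e-07). B cell genes had Cd37, a tetraspanin, higher of 17 and 3 adjusted over the list alone (0.49, 8.03e-06), and T cell genes the adaptor Skap1 and the homing receptor Ccr7 of 19 and 5 adjusted over the list alone (0.59, 2.21e-05). Erythroid genes had 0 of 13 and 9 adjusted over the list alone (1.71, 8.03e-06), and mitochondrially encoded transcripts 0 of 13 and 11 adjusted over the list alone (0.39, 1.2e-05). Alveolar macrophage genes had 3 of 22 and 7 adjusted over the list alone (0.36, 0.00265), with the integrin Itgax rising from 36.7 ± 3.52 to 89.1 ± 30.0 CPM and Abcg1 by 0.39. Each of these 8 lists had an adjusted p = 0.773 with an estimated correlation.

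Other lists called in RSBD against control lungs were the inflammasome (1 of 15 higher, median 0.38, camera adjusted p = 0.00479; lost without RSBD 3, 0.12), monocytes (1 of 25, 0.37, 0.00843; lost without RSBD 2, 0.0867), the mesothelium (0 of 12, -0.53, 0.0158; lost without RSBD 2, 0.063), and dendritic cells (3 higher and 1 lower of 21, 0.43, 0.0158; lost without control 1 or RSBD 2, highest 0.281). With an estimated correlation their adjusted p = 0.773, 0.773, 0.773 and 0.825. Oxidative phosphorylation (0 of 29, 0.17, 0.00479), cholesterol synthesis (0 of 23, -0.24, 0.00709; lost without control 2 or RSBD 2, highest 0.227), the unfolded protein response (0 of 20, -0.21, 0.0107; lost without RSBD 1, 0.0935) and alveolar type 2 cells (Chia1 and Slc26a9 lower of 22, -0.05, 0.0216; lost without control 2, RSBD 2 or RSBD 3, highest 0.325) had an adjusted p = 0.825, 0.825, 0.825 and 0.891 with an estimated correlation. Adjusted over the list alone these 8 lists had 1, 4, 0, 8 higher and 2 lower, 0, 0, 0 and 2 members. The other 22 lists were not called (camera adjusted p from 0.0571 for neutrophils to 0.989 for junctions), among them club and ciliated cells (0 called of 22 each, medians 0.07 and -0.17), cardiac muscle (0 of 18, 0.41) and immediate early genes (1 higher and 4 lower of 23). The test or the mean pointed against the median for alveolar type 1 cells, immediate early genes, club cells, adipose tissue, endothelium and junctions. Dbp and Arntl of the clock list were called at 1.85 and -0.999, with the list at 0.835. In all 18 lists were called, 14 higher and 4 lower, 0 past the threshold with an estimated correlation and 2 by fry. None of the 13 fixed genes was called, Il6 being nearest (-2.001, adjusted p = 0.0711; called without control 1, 0.023, with 0.0119 to 0.23 over all alternatives). Calls of Ccr3, Ms4a2, H2-DMa, Ciita, Ifi27l2a, Dhx58, Mcm5, Cd37, Skap1, Ccr7, Itgax and Abcg1 were lost without 2 to 8 of the 9 libraries in turn (highest 0.153, for Dhx58), a control library among them for each. Ifi27l2a also lost its call with no filter on low counts and Dhx58 with RLE scaling. Members just outside the threshold were Rrm2, Cxcr5, Epb42, Bpgm, mt-Nd5 and mt-Nd6 at 1.27, 0.57, 2.08, 0.77, 0.51 and 0.54 (adjusted p from 0.0512 to 0.0677).

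The calls of the pair of comparisons with control overlapped. Of the 296 genes higher with RSBD 263 were also higher after LPS, and of the 282 lower 259 were also lower, with 0 in opposite directions. Independent lists would share 26 and 24.3. Unchanged groups with the same control libraries shared 0.1 and 0 in simulations. Those simulations called 0.4 genes for LPS and 0.35 for LPS plus RSBD against control on average, which fixed an overlap near 0 beforehand. They are therefore no reference for what sharing the control libraries gives. Simulations with an LPS effect and no RSBD effect shared 1250 and 1100 against the 263 and 259 observed, with the larger LPS effect noted above. Fold changes correlated at 0.719 across genes, between the simulated 0.501 for unchanged groups and 0.897 for an LPS effect alone, and the covariance of 0.252 lay between 0.0554 and 0.491. The control libraries cannot be split into groups of 2, so the part that comes from sharing them was not removed. Both comparisons also set libraries with chromosome Y transcripts against libraries without, and the simulated LPS effect carries that difference. The overlap could come from it, from LPS or from both, which cannot be told apart here.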

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

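For LPS against control the 2723 calls became 597 with a fold change of at least 2 and 1532 with limma on log2(TPM + 1) without a filter. They stayed within 1.5 times in the other fits, from 1828 with the replicate block to 3792 by DESeq2. Leave-one-out counts ran from 786 (without LPS 2) to 2870 (without LPS 1). For LPS plus RSBD against LPS the 0 calls became 154 by DESeq2, 1 with only the compared groups in the fit, and 1 and 1 by limma on log2(TPM + 1) and log2(TPM + 0.1), with 0 to 4 in leave-one-out. For LPS plus RSBD against control the 578 calls became 1702 by DESeq2, which held all 578, 136 with a fold change of at least 2, 308 and 307 by limma on log2(TPM + 1) and log2(TPM + 0.1), and 137 by limma without a filter. Leave-one-out gave 94 (without control 2) to 961 (without LPS 1). Genes called in opposite directions, 0 in the main fit, numbered 129 by DESeq2, 1 with only the compared groups, 1 and 1 by limma with either pseudocount, and 0 to 4 in leave-one-out. The fold threshold lowers counts by construction. For the other changes the cause was not tested.

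The median share of the LPS change, -0.32, ran from -0.404 to -0.279 in leave-one-out and from -0.327 to -0.318 in the other fits. Against a held-out LPS library it was 0.0178 (LPS 1, reversed in sign), -0.336 (LPS 2) and -0.143 (LPS 3), and the cause was not tested. Of the 23, 19 and 18 list calls, 0, 1 and 0 remained with an estimated correlation and 6, 2 and 2 by fry. Leave-one-out gave 18 to 23, 16 to 22 and 13 to 23. Scaling by RLE or TPM changed the sign of 0 called list medians. These scalings shifted genes by a median of -0.0951 to 0.0051 log2 units. That is less than most of the list medians, so few could have changed sign.

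With the replicate block the calls were 1828, 0 and 240, and the list calls 23, 21 and 19. The replicate numbers do not pair the samples: same-number correlations ran from -0.215 to 0.122, 2 of 9 exceeded 0.1, and 1 of 9 libraries correlated best with its own number. Without the genes of chromosomes X and Y, an alternative added after the data were seen, the calls were 2657, 0 and 538.

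Over the named genes 1380 results kept their side of the threshold, 148 fell short of it and 33 passed it newly. For lists 566 kept it and 154 fell short. With 3 libraries per group a 1.5-fold change is recovered in 24% to 36% of simulated cases, and genes at a few CPM rest on few reads. The simulated sets held many planted changes, so these recoveries do not carry over to LPS plus RSBD against LPS, which had no calls.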

Other observations

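Retinoid genes were looked up after Cyp26b1, Lrat and Rarg had been seen among the changed genes. Against the libraries labelled control, LPS libraries were lower for Cyp26b1, which degrades retinoic acid (-4.95, edgeR adjusted p = 0.0094), Lrat, which esterifies retinol (-2.80, 0.00304), the retinoic acid receptor genes Rarg (-0.84, 0.00197) and Rarb (-1.04, 0.0411), the retinal reductase Dhrs3 (-0.76, 0.00955), the retinol transporter Stra6 (-1.93, 0.0415) and Aldh1a1, which makes retinoic acid (-0.42, 0.036). LPS plus RSBD libraries were lower than control for Cyp26b1, Lrat, Rarg and Dhrs3 (-5.14, -2.53, -0.68 and -0.68) but not by the test for Rarb, Stra6 and Aldh1a1 (-0.71, -1.28 and 0.02, adjusted p = 0.193, 0.189 and 0.936). Rara, Rbp4, Aldh1a2, Aldh1a3, Rdh10, Rdh11 and Bco1 were not called. Cyp26b1 varied within control, at 2209, 1045 and 508.5 CPM, while Rarg measured 154.9, 133.8 and 130.3 CPM there.

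In what follows, the tests of sex in place of LPS, of blood, of airway tissue and the splits of LPS plus RSBD with LPS were chosen only after the results they concern were seen, as were the genes of the largest split.

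The libraries labelled control hold 6, 7 and 9 reads of chromosome Y genes, where the labels give male mice. Loss of such reads in mapping or counting, without their assignment to other genes, would leave X-linked genes unchanged. The median log2 fold change of Kdm5c, Eif2s3x and Ddx3x, LPS over control, was -0.512, with all 3 called, which argues against such loss. These genes are the X-linked counterparts of Kdm5d, Eif2s3y and Ddx3y. The value therefore cannot exclude that control reads of the Y genes were assigned to them. It is also what female control mice would give, so the control libraries may come from female mice. Whether such mice were used in the control group, or the samples were exchanged for others from outside this set, was not tested, and an exchange would leave the treatment of these libraries open as well. Whether sex in place of LPS lies behind the other calls cannot be told apart, because sex and LPS are confounded here: 2647 of the 2723 calls lie outside chromosomes X and Y and could come from either or both.

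Clock genes differ between LPS plus RSBD and LPS libraries in opposite arms. The mean log2 fold change of Arntl, Npas2 and Clock was -0.645 while Dbp, Tef, Hlf, Per and Nr1d genes were higher. A shift in tissue composition that changed all clock genes alike would move both arms the same way, and -0.645 argues against that. Whether cell types differ in the levels of the arms was not tested, so other shifts in composition stay open. A different clock phase at collection, for example from a different hour of killing, may also explain the pattern, with the mean of -0.645 on the side it needs. The score of the Per and Dbp arm minus the Arntl arm was 0.076, -1.213 and 0.083 in control, -0.935, -0.377 and -0.706 in LPS and 0.578, 1.468 and 1.025 in LPS plus RSBD libraries (exact 2-sided permutation p = 0.1 for LPS plus RSBD against LPS, the smallest possible). Control 2 lies below every LPS library, so scores also spread widely within a group. An action of RSBD on the clock was not tested, and the hour of collection is not in the labels used here.

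Neutrophil transcripts are lower in LPS plus RSBD than in LPS libraries, by a list median of -1.72 (SE 0.315 over members, which are correlated). The camera call was lost with an estimated correlation (adjusted p = 0.342), and the difference in score had an exact 2-sided permutation p = 0.2. Less blood in the lungs would lower erythroid transcripts about as much, but their median was -0.00174 (SE 0.0675). A larger share of airway tissue that diluted all leukocytes alike would lower lymphocyte transcripts too, but the median over T, B and NK members was 0.35 (SE 0.0458, over correlated members). Plasma and dendritic cell lists had medians of 0.40 and 0.15. Alveolar macrophage, monocyte, and eosinophil, basophil and mast cell lists were lower (-0.22, -0.23 and -0.29), by less than neutrophils. Airway tissue that brought lymphocytes with it was not tested and stays open. The clock phase stays open: within groups the clock and neutrophil scores correlated at 0.0376 over 6 libraries (exact permutation p = 0.972, 36 arrangements), too few to decide. An effect of RSBD could also lie behind the pattern, and the score of RSBD 3 (0.422) above that of LPS 3 (0.232) remains beside it.

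With 3 against 3 there are 10 splits, so a share under 0.05 cannot be had. For LPS against control 1 of 10 splits gave as many genes (2723, highest other 0), for LPS plus RSBD against control 1 of 10 (578, highest other 1), and for LPS plus RSBD against LPS 10 of 10 (0, highest other 57), which a real count of 0 fixes beforehand. The split with 57 genes, the largest of the 10, sets LPS 1, LPS 2 and RSBD 3 against LPS 3, RSBD 1 and RSBD 2. It was picked for its count, and whether the samples hold a structure other than their group was not tested. It has 47 genes higher and 10 lower in the first set, among them Itgam, Clec4d and C5ar1 higher and Acta2, Tagln, Cnn1 and Actg2 lower. Of the 22 neutrophil list members 0 were called in it.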
